A study of Mus musculus with 30 samples.

How the data were processed

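The series holds RNA sequencing of mouse liver from 2 studies of UB-NPs, a preparation whose full name the labels do not give, in mice fed a high-fat diet. There were 30 libraries in 6 groups of 5, and groups were taken from the sample labels. RNA was extracted with TRIzol, and poly(A)-selected stranded libraries were sequenced in paired ends on a NovaSeq X Plus, per the labels' protocols.

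Per the submitters' processing notes, fastp, HISAT2, StringTie and DESeq2 were used with the mouse genome build GRCm39, without versions, parameters or the annotation release. The deposited gene table holds expected counts (estimated reads) per gene and library, which the authors did not scale to a common total. Between 4.02% and 7.03% of the genes of a library had a fractional value in it. The deposited TPM table, made by the authors, gives length-scaled transcript abundances, and each of its columns sums to the same total. A deposited table of calls, whose name gives DESeq2, lists 5977 genes that the authors called in at least 1 comparison, with the direction of each call. Its thresholds are not stated in the file or the labels. How reads shared by near-identical genes or by overlapping genes on opposite strands were counted is not stated either, so values of paralog families and antisense genes are uncertain.

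The tests used the counts. Gene IDs were taken from the count table, and 56620 of its 57180 IDs matched GENCODE release M39. This GRCm39 annotation supplied coordinates, gene types and the GC content of the longest transcript. Transcript lengths are the lengths given in the count table. Of the 56163 IDs with a symbol in both, 499 had a different symbol, and the symbols printed are those of the count table. Nuclear copies of mitochondrial genes were found with BLAST+ 2.17.0 as genes with at least 80% identity to the mitochondrial genome over at least 50% of their length. There were 29 such copies, and their counts were added to those of the 37 mitochondrial genes for the mitochondrial share of a library. Shares were compared by exact two-sided permutation tests with Benjamini-Hochberg adjustment over 6 comparisons, in Python 3.11.15 with NumPy 2.4.6, and figures were drawn with matplotlib 3.10.9. All pairs of libraries within groups, 60 in number, were checked for copies of one another, and 0 were identical.

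Total counts ranged from 17.0 to 24.3 M (mega) per library. In R 4.3.3, each study of 15 libraries was fitted on its own with edgeR 4.0.16, using filterByExpr by group, TMM normalization, robust quasi-likelihood fits with group means and the two-sided quasi-likelihood F-test. P-values were adjusted by Benjamini-Hochberg over all genes tested, and a gene was called at an adjusted p under 0.05 with no fold-change minimum. Differences of effects between the studies were tested as interaction contrasts in 1 fit of all 30 libraries. Expression is given as CPM (counts scaled to a common total) on TMM-scaled library sizes, as mean and SD over 5 libraries. Log2 fold changes are given with an approximate standard error (SE). It is the absolute log2 fold change divided by the square root of the F statistic, and is least reliable for genes near 0 counts. A fold against a group with 0 counts is a lower bound computed with a floor of 3 counts over the group, and a ratio to a group with 1 to 3 counts is given with an interval at a confidence level of 0.95. Such bounds and intervals cover counting error only.

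Gene lists for liver pathways, cell types and RNA quality, 43 in number with 772 genes, were tested with camera of limma 3.58.1 (two-sided, preset correlation of 0.01, prior count of 2, at least 5 measured members) and Benjamini-Hochberg adjustment over the lists of a comparison. The same test with a correlation estimated for each list was an alternative. A list of single genes of interest and a list for a check of the samples were not tested. Calls shared by or opposed between 2 comparisons were counted beside the number that independent lists of calls would share. For comparisons with the same control libraries, groups without any change were simulated 20 times, and the 5 controls were split into 2 and 3 in 10 fits.

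Named genes follow a rule of several parts. For each of the 4 main comparisons, the rule takes the 6 called genes with the largest rise and the 6 with the largest fall that had a symbol of a characterised gene, a mean of at least 1 CPM and every library of 1 group above every library of the other. It adds the 3 members with the smallest adjusted p of each of the 6 most significant lists and 26 genes of interest for liver lipid metabolism and inflammation. For each interaction it takes the 4 largest differences in each direction, and for opposed calls the 6 genes with the smallest adjusted p-values. The groups, comparisons, lists, rule for named genes and alternatives were chosen before the data were examined, except the alternatives that concern the mitochondrial share.

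The procedure was tested on simulated counts for each comparison, with 100 genes changed 2-fold and 100 changed 4-fold. For MC minus NC, 42% of the 2-fold and 81% of the 4-fold changes were recovered among 13130 genes. For UB minus MC these shares were 40% and 91% among 13158 genes. For HFD minus NFD they were 32% and 80% among 13788 genes, and for Uro minus HFD 31% and 92% among 13584 genes. In the interaction fits they were 7% and 73% for the diet effect and 6% and 68% for the UB-NP effect. Unchanged genes made up 3.15% to 8.15% of the calls over all 8 contrasts.

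Alternatives were the size factors of DESeq2 1.42.0, no low-count filter, the DESeq2 test, the replicate number as a block, a minimum absolute log2 fold change of 1, limma on log2(TPM + 1) for genes with a mean of at least 0.5 TPM, voom with sample quality weights, all 30 libraries in 1 fit, and each library left out in turn. After the data were seen, 3 more were added, which left out the mitochondrial genes and copies, used the mitochondrial share as a covariate, or left out the library of each group with the highest share. The authors' comparison of HFD with MC was not tested here because it compares groups of different studies. Results of 3 single genes were withheld and are not reported here, though the counts of named genes include them.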

Results

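Gene expression was measured by RNA sequencing in the livers of mice fed a standard or a high-fat diet, with or without UB-NPs given by daily oral gavage. In the prevention study, NC mice had a standard diet and water, MC mice a high-fat diet and water, and UB mice a high-fat diet and 60 mg/kg/day of UB-NPs, for 10 weeks. In the treatment study, NFD mice had a standard diet and water for 18 weeks. HFD and Uro mice became obese on 10 weeks of high-fat diet and stayed on it for 8 more weeks, HFD mice with water and Uro mice with 60 mg/kg/day of UB-NPs. The design gives 10 mice per group. Each group had 5 libraries, and each library was taken as 1 mouse, which the labels do not state. Total counts per library, in M (mega), were 17.8 ± 0.559 in NC, 18.5 ± 1.05 in MC, 18.2 ± 0.858 in UB, 17.5 ± 0.461 in NFD, 19.98 ± 1.33 in HFD and 22.3 ± 1.63 in Uro (SD, n = 5 each).

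Transcripts of mitochondrial genes and of their nuclear copies took a large and uneven share of the counts. Nearly all counts of copies came from 6 of the 29, at 1 site on chromosome 1 (GRCm39, 24651488 to 24655278). The share was 67.2 ± 4.42% in NC, 50.9 ± 12.9% in MC, 44.96 ± 4.02% in UB, 68.4 ± 10.4% in NFD, 66.1 ± 9.68% in HFD and 18.8 ± 2.82% in Uro (SD, n = 5 each). Uro differed from HFD by -47.4 percentage points and from NFD by -49.7 points. UB differed from NC by -22.2 points (exact two-sided permutation p = 0.007937 for each of the 3 differences, the smallest that 5 against 5 allow, adjusted p = 0.01587 over 6 comparisons). MC differed from NC by -16.3 points (exact permutation p = 0.04762, adjusted p = 0.07143). The differences of -5.96 points in UB minus MC and of -2.29 points in HFD minus NFD did not exceed the spread (exact permutation p = 0.3651 and p = 0.7302). The counts left for all other genes averaged 5.84 M in NC, 9.20 M in MC, 10.0 M in UB, 5.50 M in NFD, 6.85 M in HFD and 18.1 M in Uro. They ranged from 3.14 to 19.7 M over the libraries.

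**Figure D1:**
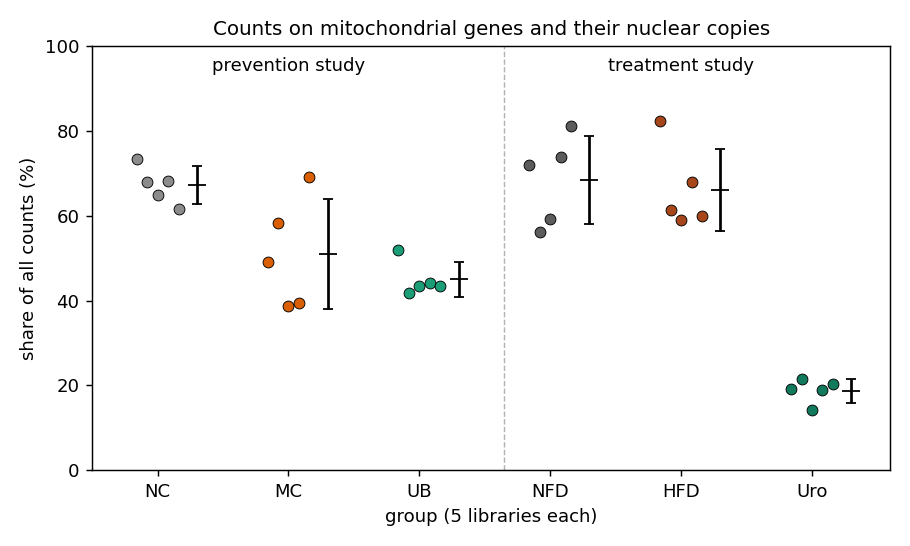
Share of the counts from mitochondrial genes and their nuclear copies (percent) in each library, by group; points are libraries and bars show the mean and SD of 5. The Uro libraries lie lowest, at 18.8 ± 2.82%, and the MC libraries spread over the widest range of the prevention study.

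The comparison of MC with NC asked what 10 weeks of high-fat diet did to liver expression. Genes of lipid droplets and lipid uptake were higher in MC livers, where 13 of 23 measured members rose, 0 fell and 10 did not pass the test. Cd36, a fatty acid transporter, rose from 10.1 ± 3.12 to 53.0 ± 14.5 CPM (SD, n = 5 each), a log2 fold change of 2.39 ± 0.22 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 4.26e-07). Cidea, which encodes a lipid droplet protein (ENSMUSG00000024526, chromosome 18, 67476317 to 67501224), had 0 counts in NC and 4.51 ± 2.46 CPM in MC, at least 110-fold higher (edgeR adjusted p = 8.8e-06). Cidec, another lipid droplet protein, and Scd1, a fatty acid desaturase, rose by 2.84 ± 0.63 and 1.56 ± 0.35 on the log2 scale (edgeR adjusted p = 0.0125 and 0.00713). Among adipose markers, 3 of 6 rose, among them Cidea of the list just described and Cfd, the adipocyte protein adipsin, which went from 0.853 ± 0.937 to 106 ± 60.5 CPM (edgeR adjusted p = 0.000422). Adjusted over the list alone, 14 lipid droplet genes and 3 adipose markers rose. The lists were called higher (camera adjusted p = 1.55e-08 and 0.000437) and stayed so with an estimated correlation (adjusted p = 0.0366 for both).

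Genes of the urea cycle and amino acid metabolism were lower in MC, with 15 of 24 members falling and 0 rising. Arg1, the arginase of the urea cycle (ENSMUSG00000019987, chromosome 10, 24791118 to 24803817), went from 1286 ± 228 to 441 ± 83.7 CPM, and Gls2, the liver glutaminase, from 227 ± 19.5 to 82.7 ± 14.9 CPM (edgeR adjusted p = 2.52e-05 and 6.15e-06). Adjusted over the list alone, 16 members fell and 1 rose. The list had a median log2 fold change of -0.94 (camera adjusted p = 1.89e-11, but adjusted p = 0.128 with an estimated correlation). Cholesterol synthesis genes were also lower, 6 of 24 falling and 1 rising, or 14 and 2 when adjusted over the list alone. This list held its call (camera adjusted p = 7.13e-07, and adjusted p = 0.0366 with an estimated correlation). Idi1, an isomerase of the pathway, fell by 3.20 on the log2 scale, Stard4, a sterol carrier, by 2.05 and Fdps, farnesyl diphosphate synthase, by 1.47 (edgeR adjusted p = 4.85e-05, 1.26e-05 and 0.00026).

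Markers of pericentral hepatocytes were higher and those of periportal hepatocytes lower in MC. Of 12 pericentral markers 10 rose, or all 12 when adjusted over the list alone. The median was 1.41 (camera adjusted p = 2.6e-09; adjusted p = 0.0901 with an estimated correlation). The glutamate transporter Slc1a2 rose by 1.64 ± 0.27 on the log2 scale (edgeR adjusted p = 0.000853). Of 12 periportal markers 5 fell, or 7 adjusted over the list alone. The members' median was -0.76 (camera adjusted p = 3.83e-05; adjusted p = 0.0672 with an estimated correlation). Etnppl fell by 2.77 and Gldc, of the glycine cleavage system, by 1.38 on the log2 scale (edgeR adjusted p = 0.000665 and 0.00134). Of 13 mitochondrially encoded genes 7 fell, or 11 adjusted over the list alone. The list's median was -0.955 (camera adjusted p = 7.13e-07; adjusted p = 0.394 with an estimated correlation), and the call ended with the mitochondrial share as a covariate (camera adjusted p = 0.727). That share holds the counts of these same genes, so the adjustment is circular for them. Among them, mt-Cytb fell by 1.12 on the log2 scale (edgeR adjusted p = 0.0216), a call that ended without NC replicate 1 (edgeR adjusted p = 0.0596) or MC replicate 3 (0.0567). Among the largest single changes, Themis, a gene of T cell development, rose by 4.25 ± 0.44 and Gpnmb, a macrophage glycoprotein, by 5.88 ± 1.28 (edgeR adjusted p = 3.48e-06 and 0.0114). Cxcl13, a B cell chemokine, fell by 3.94 on the log2 scale (edgeR adjusted p = 0.00118).

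In all, 1645 of 13498 genes were called, 898 higher and 747 lower in MC (edgeR quasi-likelihood, Benjamini-Hochberg), and 15 of 39 lists, of which 3 held with an estimated correlation. The authors' deposited calls held 851 genes for this comparison, 708 of them also called here in the same direction and 0 in the opposite one. The count was 923 without NC replicate 2 and 1051 without MC replicate 3. With the mitochondrial share as a covariate it was 377 (259 higher, 118 lower). Over the 1645 genes the median absolute log2 fold change then went from 0.935 to 0.876 and the median SE from 0.234 to 0.308, with 99.9% in the same direction. TPM values gave 2080 genes higher and 69 lower, with a median log2 fold change of all genes of 0.344, against 0.026 with counts.

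The comparison of UB with MC asked what UB-NPs did when given alongside the high-fat diet. Clock genes stood out, with 4 of 20 rising, 0 falling and 16 not passing the test, or 9 rising and 3 falling when adjusted over the list alone. Per3, a circadian clock gene (ENSMUSG00000028957, chromosome 4, 151081373 to 151129140), rose from 1.33 ± 0.805 to 8.91 ± 1.78 CPM, a log2 fold change of 2.72 ± 0.48 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.011; 0.0522 without MC replicate 3). Ciart, a repressor within the clock, rose by 4.11 ± 0.85 and Nr1d2, a nuclear receptor of the clock, by 1.02 ± 0.23 (edgeR adjusted p = 0.028 and 0.0354). The list had a median of 0.88 (camera adjusted p = 0.000132; adjusted p = 0.231 with an estimated correlation). Acot3, a peroxisomal acyl-CoA thioesterase, rose from 6.16 ± 1.90 to 29.1 ± 7.89 CPM and Coq10b, which serves coenzyme Q function, from 11.4 ± 1.78 to 32.5 ± 4.90 CPM (edgeR adjusted p = 0.011 and 9.19e-05).

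**Figure D2:**
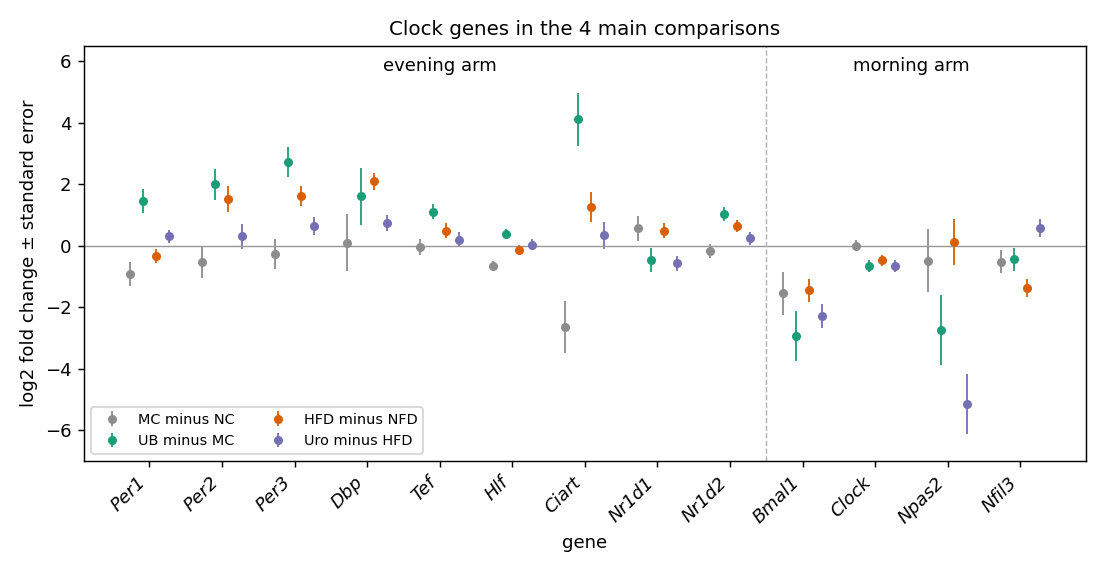
Log2 fold change with SE of 13 clock genes in the 4 main comparisons, grouped by whether expression in mouse liver peaks towards evening or towards morning. In UB against MC, 8 of 9 evening genes lay above 0 and 4 of 4 morning genes lay under 0.

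Cldn1, the tight junction protein claudin-1 (ENSMUSG00000022512, chromosome 16, 26175392 to 26190596), went from 24.8 ± 11.9 CPM in MC to 4.92 ± 0.464 CPM in UB (edgeR adjusted p = 9.15e-05). Insig2, which retains the sterol sensor in the endoplasmic reticulum, went from 113 ± 32.2 to 33.8 ± 7.49 CPM, and Slc30a10, a manganese exporter, from 7.03 ± 2.72 to 1.59 ± 0.453 CPM (edgeR adjusted p = 0.000867 and 0.000426). Apoa1, the main protein of high-density lipoprotein, fell by 1.15 on the log2 scale and was the single called member of 21 lipoprotein genes, and the single one adjusted over the list alone (edgeR adjusted p = 0.0298). That list had a median of -0.33 (camera adjusted p = 0.00179; adjusted p = 0.662 with an estimated correlation). Selenbp2, a male-biased liver gene, fell by 2.16 on the log2 scale (edgeR adjusted p = 0.011), alone among the 18 male-biased genes (2 lower adjusted over the list alone), whose median was -0.79 (camera adjusted p = 0.00202; adjusted p = 0.814 with an estimated correlation).

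Of 26 interferon response genes 0 were called in UB against MC over all genes tested, but 13 were higher when adjusted over the list alone. Their median was 0.95 (camera adjusted p = 1.75e-06; adjusted p = 0.814 with an estimated correlation). Their member Mx1, an antiviral protein, had 1.99 ± 1.02 CPM in MC and 5.37 ± 2.42 CPM in UB, a log2 fold change of 1.43 ± 0.40 (edgeR adjusted p = 0.118). The same list was lower in MC against NC, with 6 members falling and 0 rising, or 8 and 1 adjusted over the list alone, and a median of -0.774 (camera adjusted p = 3.83e-05; adjusted p = 0.588 with an estimated correlation). In UB against NC 0 members were called and the median was 0.149 (camera adjusted p = 0.571; adjusted p = 0.953 with an estimated correlation). MC minus NC and UB minus MC share the MC libraries, which alone favours opposite directions in the 2 comparisons. Markers of Kupffer macrophages went the same ways as the interferon genes in both. In MC against NC 3 of 14 fell, or 3 adjusted over the list alone, with a median of -0.444 (camera adjusted p = 0.0118; adjusted p = 0.588 with an estimated correlation), and in UB against MC 0 were called over all genes or the list alone, with a median of 0.348 (camera adjusted p = 0.0117; adjusted p = 0.868 with an estimated correlation). The first of these calls ended without MC replicate 2 (0.0657) and with the mitochondrial share as a covariate (0.369), the second without MC replicate 2 (0.111) or UB replicate 1 (0.246). Markers of infiltrating and lipid-associated macrophages went the other way in MC against NC, where 5 of 13 rose and 0 fell, or 7 and 0 adjusted over the list alone, with a median of 1.29 (camera adjusted p = 0.0137; adjusted p = 0.394 with an estimated correlation). That call ended without MC replicate 5 (0.051), without the library of each group with the highest mitochondrial share (0.0936), with voom (0.165) and with TPM values (0.648). In UB against MC 0 of them were called over all genes or the list alone, with a median of 0.048 (camera adjusted p = 0.495; adjusted p = 0.956 with an estimated correlation). Of 23 lipid droplet genes 0 were called (2 lower adjusted over the list alone; camera adjusted p = 0.00179; adjusted p = 0.662 with an estimated correlation). Cidea, at 0.991 ± 0.514 CPM in UB, had a log2 fold change of -2.18 ± 0.51 (edgeR adjusted p = 0.0608). The 13 mitochondrially encoded genes had a median of -0.61 with 0 called, or 2 lower adjusted over the list alone (camera adjusted p = 0.000132; adjusted p = 0.814 with an estimated correlation). Srebf1, Fasn, Scd1 and Cd36, genes of lipid synthesis and uptake, had log2 fold changes of 0.19, -0.50, -0.81 and -0.46 (edgeR adjusted p = 0.921, 0.544, 0.37 and 0.413).

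In all, 82 of 13498 genes were called, 28 higher and 54 lower in UB (edgeR quasi-likelihood, Benjamini-Hochberg), and 1446 had an unadjusted p under 0.05. Of 39 lists 10 were called, 0 of them with an estimated correlation. The authors' calls held 128 genes, 48 of them shared in direction. The count was 27 without MC replicate 2, 20 without MC replicate 3, 29 without UB replicate 1, 34 without UB replicate 2, 29 without UB replicate 3 and 53 without UB replicate 4. The DESeq2 test gave 232 and no low-count filter 129. TPM values gave 71 genes higher and 2 lower, with a median log2 fold change of all genes of 0.331, against 0.003 with counts. The call of Ciart ended without MC replicate 1, 2, 3 or 4 or UB replicate 1, 2, 3 or 4, at edgeR adjusted p of 0.0514 to 0.115. Those of Nr1d2 and Apoa1 ended without MC replicate 2 or 3 or UB replicate 1, 2 or 3, and Nr1d2 also without MC replicate 5, at edgeR adjusted p of 0.0723 to 0.124 and 0.0789 to 0.119.

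Against NC, UB livers had 1053 genes called, 603 higher and 450 lower (edgeR quasi-likelihood, Benjamini-Hochberg), and 11 of 39 lists, of which 3 held with an estimated correlation. Those 3 were cholesterol synthesis with 6 of 24 falling and 0 rising (14 and 0 adjusted over the list alone), periportal markers with 5 of 12 falling and 0 rising (6 and 0) and adipose markers with 2 of 6 rising and 0 falling (3 and 0), at camera adjusted p of 4.73e-07, 1.12e-06 and 0.000823, and 0.0329 for each with an estimated correlation. All 13 mitochondrially encoded genes fell, also adjusted over the list alone, with a median of -1.515 (camera adjusted p = 1.41e-13; adjusted p = 0.149 with an estimated correlation). Markers of sinusoidal endothelial cells had 6 of 14 members rising and 0 falling, or 7 adjusted over the list alone. This list had a median of 0.70 (camera adjusted p = 0.000363; adjusted p = 0.0965 with an estimated correlation). The count was 650 without NC replicate 1, 583 without NC replicate 2, 696 without NC replicate 3, 1589 without NC replicate 5, 689 without UB replicate 3, 550 without UB replicate 4 and 561 without UB replicate 5. It was 71 with the mitochondrial share, which separated the groups completely, as a covariate. The median absolute log2 fold change of the called genes then went from 0.961 to 0.767 and the median SE from 0.235 to 0.356, with 99.1% in the same direction. TPM values gave 6861 higher and 43 lower, with a median log2 fold change of all genes of 0.68, against 0.007 with counts.

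Genes that the diet moved one way and UB-NPs the other numbered 39 in the prevention study, 24 higher then lower and 15 lower then higher. Independent lists of calls would share 3.59 and 1.55. Akr1c19, an aldo-keto reductase (ENSMUSG00000071551, chromosome 13, 4278699 to 4302842), went from 29.0 ± 6.39 CPM in NC to 11.9 ± 3.91 in MC and 31.7 ± 7.36 in UB (edgeR adjusted p = 0.0011 and 0.00379). Atp2a2, the calcium pump of the endoplasmic reticulum, went from 33.8 ± 6.25 to 61.6 ± 12.8 and 30.9 ± 7.05 CPM (edgeR adjusted p = 0.00433 and 0.011). Rbm3, an RNA-binding protein induced by cold, fell by 1.04 on the log2 scale with the diet and rose by 0.91 with UB-NPs (edgeR adjusted p = 0.000766 and 0.0156; the second call ended at 0.051 to 0.061 without MC replicate 2 or 3 or UB replicate 1). Across genes, which are not independent replicates, the log2 fold changes had r = -0.455 and covariance -0.179. Simulated groups without change, with the MC libraries simulated as well and shared by both comparisons, gave r = -0.496, covariance -0.0886 and 0 opposed genes. Permuted labels, with as many genes of lowest p as the real labels called, gave 7 to 67 opposed genes, and 25 of 40 permutations, the real one included, reached 39. With the MC libraries split between the comparisons, the values were r = -0.120, covariance -0.129 and 4.15 opposed genes on average. The count was 25 without NC replicate 1, 21 without NC replicate 4, 9 without MC replicate 2 and 6 without MC replicate 3. It was 11 without UB replicate 1, 15 without UB replicate 2, 13 without UB replicate 3 and 24 without UB replicate 4.

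The comparison of HFD with NFD asked what the longer high-fat feeding of the treatment study did. Immune genes were higher in HFD livers. Of 13 markers of infiltrating and lipid-associated macrophages 11 rose, or 12 adjusted over the list alone. Their median was 2.47 (camera adjusted p = 7.87e-10; adjusted p = 0.0761 with an estimated correlation). Trem2, a lipid receptor of macrophages (ENSMUSG00000023992), rose from 0.615 ± 0.381 to 10.3 ± 3.76 CPM, and Gpnmb from 0.106 ± 0.161 to 31.0 ± 17.7 CPM (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 3.34e-06 and 4.48e-05). Of 26 interferon response genes 17 rose, or 20 adjusted over the list alone. The median was 0.98 (camera adjusted p = 7.87e-10; adjusted p = 0.0528 with an estimated correlation), against -0.774 in MC minus NC, and the difference between the studies was not tested for the list. Isg15, a ubiquitin-like protein, rose by 2.32 ± 0.31 and Mx1 by 1.94 ± 0.35 (edgeR adjusted p = 7.44e-05 and 0.00119). All 8 antigen presentation genes of class II rose, also adjusted over the list alone (camera adjusted p = 9.03e-08; adjusted p = 0.0992 with an estimated correlation). So did 12 of 23 cytokine and NF-kB genes, or 13 with 1 falling adjusted over the list alone (camera adjusted p = 1.3e-05; adjusted p = 0.0528 with an estimated correlation). Lcn2, which encodes lipocalin-2, rose by 3.70 ± 0.69 and the chemokine Ccl2 by 2.24 ± 0.69 (edgeR adjusted p = 0.00377 and 0.0348; the Ccl2 call ended at 0.0579 to 0.0913 without NFD replicate 1 or 3 or HFD replicate 3, 4 or 5). Immediate-early genes, whose transcripts also rise during tissue handling, had 7 of 13 members rising, 7 as well adjusted over the list alone (camera adjusted p = 0.000116; adjusted p = 0.0761 with an estimated correlation). Il1b, an inflammatory cytokine, had a log2 fold change of -1.24 ± 0.47 (edgeR adjusted p = 0.0812).

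Male-biased liver genes were lower in HFD livers, with 14 of 18 falling and 0 rising, or 16 and 1 adjusted over the list alone. Their median log2 fold change was -1.38 (camera adjusted p = 4.48e-10, or 0.0761 with an estimated correlation). In MC against NC the male-biased list had been called higher (camera adjusted p = 0.0382, or 0.63 with an estimated correlation). That call ended in 5 of 15 fits with 1 library left out and with the mitochondrial share as a covariate (camera adjusted p = 0.851). The difference between the studies was not tested for this list. Mup7, a major urinary protein of a family whose near-identical members make single values uncertain, went from 4372 ± 2901 to 62.9 ± 103 CPM (edgeR adjusted p = 0.01). Serpina1e, of another such family, went from 4646 ± 3029 to 96.5 ± 82.8 CPM (edgeR adjusted p = 0.00152). Hsd3b5, a male-specific steroid dehydrogenase, went from 19.0 ± 4.37 to 0.369 ± 0.763 CPM (edgeR adjusted p = 0.00698). Cyp2a4, a female-biased cytochrome with close paralogs, had 0 counts in NFD and 4.79 ± 3.90 CPM in HFD, at least 110-fold higher (edgeR adjusted p = 0.0256, or 0.0519 without HFD replicate 4). The list of female-biased genes was not among the 19 lists called in this comparison.

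Lists of amino acid metabolism, cholesterol synthesis, oxidative phosphorylation and fatty acid oxidation were lower in HFD livers, and that of lipid droplets and lipid uptake was higher. Of 24 urea cycle and amino acid genes 14 fell and 0 rose, or 19 adjusted over the list alone. The members' median was -0.995 (camera adjusted p = 3.12e-14; adjusted p = 0.0992 with an estimated correlation). Got1, an aspartate aminotransferase, went from 122 ± 42.7 to 21.3 ± 6.70 CPM (edgeR adjusted p = 4.48e-05). Of 25 cholesterol synthesis genes 17 fell, or 18 falling and 1 rising adjusted over the list alone. The list's median was -1.06 (camera adjusted p = 1.06e-11; adjusted p = 0.0761 with an estimated correlation). Fdps went from 32.2 ± 16.2 to 5.75 ± 1.77 CPM (edgeR adjusted p = 8.21e-05). Of 27 nuclear genes of oxidative phosphorylation 13 fell, or 17 adjusted over the list alone. This list had a median of -0.69 (camera adjusted p = 1.14e-08; adjusted p = 0.242 with an estimated correlation). Ndufv1 of complex I went from 54.3 ± 10.7 to 22.6 ± 5.26 CPM (edgeR adjusted p = 0.000395). Of 34 genes in the list of fatty acid oxidation, which includes PPARA targets, 14 fell and 1 rose, or 20 and 4 adjusted over the list alone (camera adjusted p = 8.04e-07, or 0.246 with an estimated correlation). In MC against NC this list had been called higher (camera adjusted p = 0.0137, or 0.672 with an estimated correlation). That call ended in 3 of 15 fits with 1 library left out and with the mitochondrial share as a covariate (camera adjusted p = 0.235). The difference between the studies was not tested for it. Of 23 lipid droplet genes 7 rose and 1 fell, or 11 and 2 adjusted over the list alone, with a median of 0.541 (camera adjusted p = 0.00386; adjusted p = 0.312 with an estimated correlation). Of 24 genes of fatty acid and triglyceride synthesis 5 rose and 4 fell, or 8 and 4 adjusted over the list alone (camera adjusted p = 0.462; adjusted p = 0.78 with an estimated correlation). Cd36 and Cidec rose by 2.37 ± 0.25 and 3.15 ± 0.31 (edgeR adjusted p = 3.74e-06 and 2.59e-06). Srebf1 and Pparg, regulators of fat synthesis and storage, rose by 1.21 ± 0.23 and 1.15 ± 0.27 (edgeR adjusted p = 0.0014 and 0.00746). Ppara, the receptor that drives fatty acid oxidation, fell by 1.09 on the log2 scale (edgeR adjusted p = 0.00288). Cidea had 0 counts in NFD and 1.61 ± 2.02 CPM in HFD (edgeR adjusted p = 0.0801).

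In all, 1863 of 14163 genes were called, 1019 higher and 844 lower in HFD (edgeR quasi-likelihood, Benjamini-Hochberg), and 19 of 38 lists, 0 of them with an estimated correlation. The authors' calls held 1274 genes, 1104 of them shared in direction. The count was 1178 without HFD replicate 4 and 1108 without HFD replicate 5. TPM values gave 575 genes, 491 higher and 84 lower, with a median log2 fold change of all genes of 0.192, against 0.027 with counts. In 1 fit of all 30 libraries 811 were higher and 1205 lower.

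**Figure D3:**
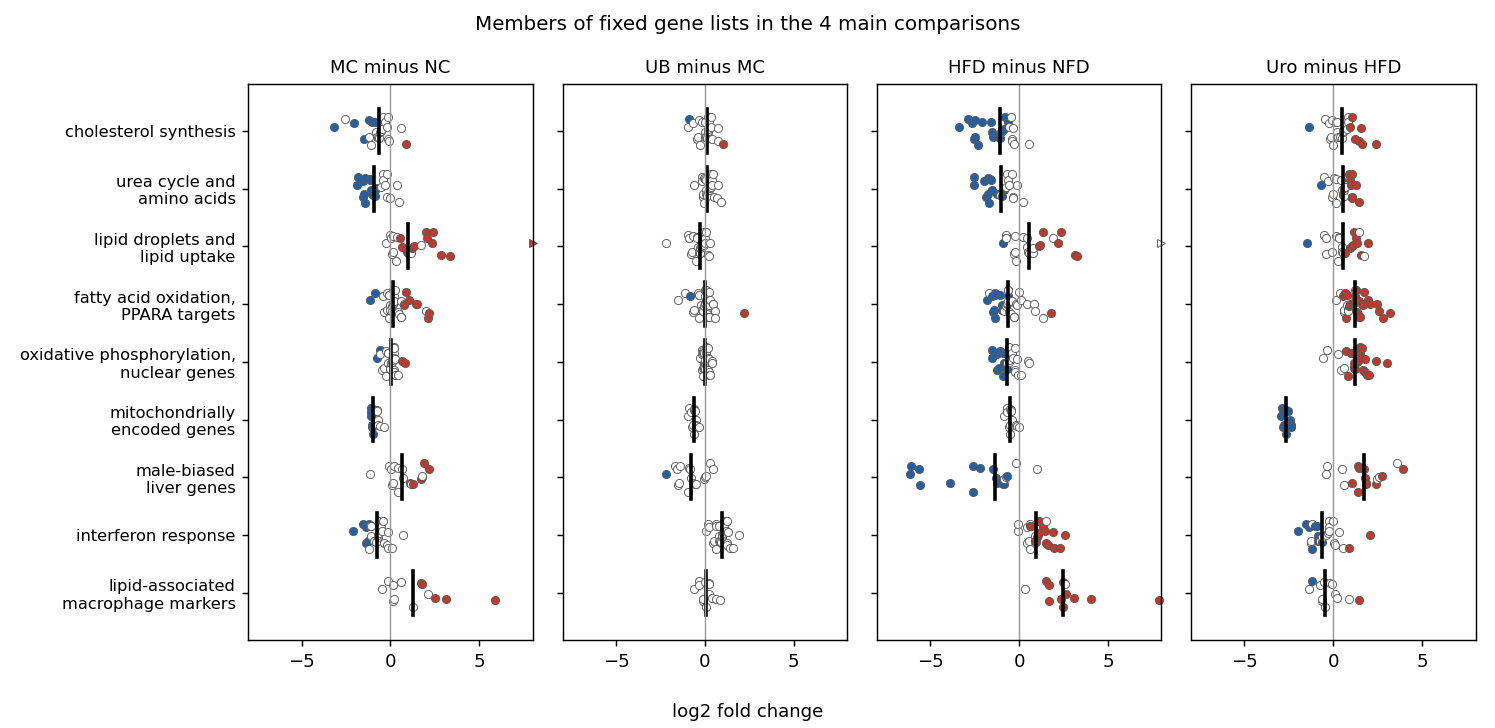
Log2 fold changes of the members of 9 gene lists in the 4 main comparisons; each point is a gene, red and blue points were called higher and lower, white points were not called, black bars are medians and triangles mark values beyond the axis. Fatty acid oxidation genes and PPARA targets had a median of 1.22 in Uro against HFD, and mitochondrially encoded genes a median of -2.66.

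The comparison of Uro with HFD asked what UB-NPs did in mice that were already obese. Genes of fatty acid oxidation and PPARA targets, which form 1 list, were higher in Uro livers, where 27 of 34 rose, 0 fell and 7 did not pass the test, or 30 rose adjusted over the list alone. Acaa2, the mitochondrial thiolase of fatty acid oxidation (ENSMUSG00000036880, chromosome 18, 74911948 to 74953492), rose from 96.6 ± 23.2 to 528 ± 78.6 CPM, a log2 fold change of 2.45 ± 0.24 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 1.19e-06). Acadvl and Hadhb, enzymes of the same pathway, rose by 1.72 ± 0.22 and 1.24 ± 0.18 (edgeR adjusted p = 9.34e-06 and 3.94e-05). Nuclear genes of oxidative phosphorylation rose too, 22 of 27 over all genes tested and 24 adjusted over the list alone, while all 13 mitochondrially encoded genes fell. Ndufa4, a nuclear-encoded respiratory chain subunit, rose from 29.3 ± 9.34 to 237 ± 47.8 CPM, and mt-Co2, a mitochondrially encoded subunit of cytochrome c oxidase, went from 861 ± 420 to 120 ± 14.4 CPM (edgeR adjusted p = 1.02e-06 and 3.89e-06). The lists had medians of 1.22 for fatty acid oxidation, 1.22 for oxidative phosphorylation and -2.66 for the mitochondrially encoded genes (camera adjusted p = 1.91e-14, 2.03e-14 and 2.03e-14; adjusted p = 0.34 for each with an estimated correlation). With the mitochondrial share as a covariate the first 2 lists were still called (camera adjusted p = 0.00765 and 0.000206), while the direction of the mitochondrially encoded genes turned (0.446). For the mitochondrially encoded genes the adjustment is circular, since the share holds their own counts. Outside mitochondrial genes, the fold changes of called genes, which are not independent replicates, had a Spearman correlation of -0.423 with transcript length. Ndufa4 has a length of 452 bases. The list tests did not adjust for length, and its share in the rise of these lists was not tested.

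General and pericentral hepatocyte markers were higher in Uro livers as well, and periportal markers went both ways. Of 11 hepatocyte markers 9 rose and 0 fell, or 9 and 1 adjusted over the list alone. Their median was 1.37 (camera adjusted p = 1.8e-05; adjusted p = 0.376 with an estimated correlation). Of 12 pericentral markers 8 rose and 0 fell, or 9 and 0 adjusted over the list alone (camera adjusted p = 0.00116; adjusted p = 0.437 with an estimated correlation). Of 12 periportal markers 4 rose and 2 fell, or 4 and 5 adjusted over the list alone, with a median of -0.369 (camera adjusted p = 0.856; adjusted p = 0.966 with an estimated correlation). F2, prothrombin, went from 149 ± 87.2 to 650 ± 56.8 CPM (edgeR adjusted p = 4.4e-05). Of 18 male-biased genes 11 rose, or 12 adjusted over the list alone. The median was 1.74 (camera adjusted p = 9.21e-06; adjusted p = 0.376 with an estimated correlation). Gstp1, a glutathione transferase with close paralogs, went from 304 ± 38.6 to 2037 ± 828.9 CPM (edgeR adjusted p = 1.26e-05). Of 27 xenobiotic metabolism genes 15 rose and 1 fell, or 16 and 1 adjusted over the list alone (camera adjusted p = 3.41e-05; adjusted p = 0.437 with an estimated correlation). Ugt1a1, the bilirubin transferase, rose by 1.89 ± 0.24 (edgeR adjusted p = 7.8e-06). Cyp7b1, an oxysterol hydroxylase, rose from 4.89 ± 4.17 to 53.6 ± 23.2 CPM (edgeR adjusted p = 0.000199). Plin2, a lipid droplet coat protein, rose from 81.7 ± 27.9 to 319 ± 65.4 CPM (edgeR adjusted p = 2.25e-05). Of 23 lipid droplet genes 9 rose and 1 fell, or 11 and 1 adjusted over the list alone, and of 21 lipoprotein genes 9 rose and 2 fell, or 10 and 2 (camera adjusted p = 0.00564 and 0.00433; adjusted p = 0.437 for both with an estimated correlation). Both lists had lain lower in UB against MC, and the difference between the studies was not tested for them. Saa1, an acute phase protein with close paralogs, rose by 2.85 ± 0.67 and Cyp1a2, a cytochrome induced through the aryl hydrocarbon receptor, by 1.84 ± 0.37 (edgeR adjusted p = 0.00646 and 0.00107). Of 26 interferon response genes 9 fell and 2 rose, or 11 and 2 adjusted over the list alone. The members' median was -0.63 (camera adjusted p = 0.0122, or 0.437 with an estimated correlation). The cytokine and NF-kB list was also called lower (camera adjusted p = 0.0379, or 0.431 with an estimated correlation). That call ended with the mitochondrial share as a covariate (0.963), with TPM values (0.0555) and in 3 of 15 fits with 1 library left out. The lipid-associated macrophage and class II lists, higher in HFD against NFD, were not among the 19 lists called here. With the mitochondrial share as a covariate the calls of the hepatocyte, pericentral, male-biased, xenobiotic, interferon, lipid droplet and lipoprotein lists ended (camera adjusted p = 0.176, 0.375, 0.321, 0.987, 0.676, 0.987 and 0.493), and the direction of the pericentral, xenobiotic and lipoprotein lists turned. TPM values ended the calls of the pericentral, xenobiotic, lipid droplet and lipoprotein lists (0.104, 0.0555, 0.0806 and 0.158). Leaving out the library of each group with the highest share ended that of the interferon list (0.0571).

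Smaller differences were near the threshold. Cpt1a, an enzyme of fatty acid oxidation, rose by 0.56 ± 0.19 (edgeR adjusted p = 0.0341), but the call ended without HFD replicate 1, 4 or 5 or Uro replicate 1, 4 or 5, at edgeR adjusted p of 0.0572 to 0.11. Scd1 fell by 0.84 and Pck1, of gluconeogenesis, by 0.68 on the log2 scale (edgeR adjusted p = 0.0453 and 0.0191), but TPM values gave 0.29 and 0.42. The call of Scd1 ended without NFD replicate 1, 2 or 3, HFD replicate 1, 3 or 4 or Uro replicate 1, 2, 3 or 4, at edgeR adjusted p of 0.0523 to 0.202, and that of Pck1 without Uro replicate 3 or 4 (0.0508 and 0.0594). Transcripts that were nearly absent from Uro libraries included Ulk4, a kinase-like gene, at 14.1 ± 4.19 CPM in HFD and 0.244 ± 0.214 CPM in Uro (edgeR adjusted p = 1.02e-06). The pseudogene Morf4l1-ps1 (chromosome 16, 24348144 to 24349112) and the antisense gene Sardhos (chromosome 2, 27079394 to 27124722) had 0 counts in Uro. They were at least 192-fold and at least 156-fold lower than in HFD (edgeR adjusted p = 8.6e-05 and 4.07e-06), and are uncertain because a parent gene or an overlapping gene shares their sequence.

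In all, 3836 of 14163 genes were called, 2174 higher and 1662 lower in Uro (edgeR quasi-likelihood, Benjamini-Hochberg), and 19 of 38 lists, 0 of them with an estimated correlation. The authors' calls held 2852 genes, 2155 of them shared in direction. The mitochondrial share separated the groups completely. With it as a covariate 2 genes were called and the sign of Fam221b, mt-Nd6 and Cyp1a2 turned, though the share holds the counts of mt-Nd6 itself. Over the 3836 genes the median absolute log2 fold change went from 1.07 to 0.753 and the median SE from 0.248 to 0.612, with 78.9% in the same direction. The median log2 fold change of all genes was -0.076, against -0.107 with the size factors of DESeq2 and 0.744 with TPM values. TPM values gave 7191 genes higher and 123 lower. Against NFD, where the share separated the groups as well, Uro livers had 4027 genes called, 2281 higher and 1746 lower, or 0 with the covariate, where the median absolute log2 fold change went from 1.14 to 0.77 and the median SE from 0.265 to 0.677. Of 38 lists 22 were called, 0 of them with an estimated correlation. Cell cycle genes had 9 of 21 members rising and 1 falling, or 11 and 1 adjusted over the list alone (camera adjusted p = 0.00221; adjusted p = 0.392 with an estimated correlation). TPM values gave 8972 genes higher and 168 lower, with a median log2 fold change of all genes of 0.968, against 0.032 with counts. In 1 fit of all 30 libraries 2032 were higher and 2081 lower.

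Genes that moved one way with the diet and the other with UB-NPs numbered 648 in the treatment study, 237 higher then lower and 411 lower then higher, where independent lists of calls would share 119.6 and 129.6. In both comparisons 122 genes moved the same way. Lpl, lipoprotein lipase (ENSMUSG00000015568, chromosome 8, 69284603 to 69360100), went from 39.0 ± 9.68 CPM in NFD to 380 ± 82.2 in HFD and 138 ± 24.6 in Uro (edgeR adjusted p = 3.67e-08 and 5.16e-05). Fbp1, the gluconeogenic fructose bisphosphatase, went from 186 ± 45.4 to 54.9 ± 17.1 and 157 ± 46.9 CPM (edgeR adjusted p = 0.00026 and 0.000228). Apom, an apolipoprotein, fell by 1.93 on the log2 scale with the diet and rose by 1.83 ± 0.29 with UB-NPs (edgeR adjusted p = 0.000245 and 7.95e-05). C8b, of the complement, fell by 2.20 and rose by 1.64 ± 0.27 (edgeR adjusted p = 2.9e-05 and 0.000107). H2-M2, a class I-like histocompatibility gene with 2 counts in NFD, was higher in HFD by a ratio of 114 (interval 31.3 to 945) and fell by 3.23 on the log2 scale in Uro (edgeR adjusted p = 3.15e-05 and 0.00021). Across genes, which are not independent replicates, r was -0.288 and the covariance -0.242. Simulated groups without change gave r = -0.498, covariance -0.0792 and 0 opposed genes. Permuted labels, counted as in the prevention study, gave 171 to 1471, and 30 of 40 permutations reached 648. With the HFD libraries split, the values were r = -0.103, covariance -0.130 and 168.3 opposed genes on average. The count was 383 without HFD replicate 4, 330 without HFD replicate 5 and 0 with the mitochondrial share as a covariate.

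Between the studies, 306 genes were called in the same direction with the diet, 154 higher and 152 lower, where independent lists would share 61.9 and 46.9. The 306 include Cd36, Cidec, Scd1, Gpnmb, Arg1, Gls2, Idi1, Stard4, Fdps and Pck1 named above. In opposite directions 47 were called. With UB-NPs, 30 genes were called in the same direction, 8 higher and 22 lower, where independent lists would share 4.55 and 6.58, and 4 in opposite directions. Across genes, which are not independent replicates, the diet effects had r = 0.251 and the UB-NP effects r = 0.098. The shared diet count was 153 with the mitochondrial share as a covariate, 166 without the library of each group with the highest share, 136 with TPM values and 463 with the DESeq2 test. The shared UB-NP count was 99 with the DESeq2 test and 52 with TPM values. It was 12 without MC replicate 2, 11 without MC replicate 3, 14 without UB replicate 1, 16 without UB replicate 2, 15 without UB replicate 3 and 0 with the mitochondrial share as a covariate.

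Tests of the difference itself called 801 of 14784 genes for the diet effect, 295 more positive and 506 more negative in the treatment study (edgeR quasi-likelihood, Benjamini-Hochberg). Mup7, of the urinary protein family whose near-identical members make single values uncertain, had a log2 fold change of 1.14 ± 0.80 in the prevention study (edgeR adjusted p = 0.396) and of -6.12 ± 1.33 in the treatment study (0.01), a difference of -7.30 ± 1.51 in the common fit (edgeR adjusted p = 0.0073). Evi2b, a leukocyte membrane protein, and Cxcl1, a neutrophil chemokine, differed by 5.02 ± 0.91 and 4.79 ± 1.07 (edgeR adjusted p = 0.0021 and 0.0103). For the UB-NP effect 1818 genes were called, 1263 more positive and 555 more negative, among them Mup15 at 6.77 ± 1.47 and Ulk4 at -5.48 ± 1.24 (edgeR adjusted p = 0.00313 and 0.0042). The diet count was 495 without MC replicate 3, 500 without MC replicate 4, 1205 without MC replicate 5 and 499 without NFD replicate 2. It was 1383 without NFD replicate 5, 1220 without HFD replicate 2, 519 without HFD replicate 4 and 524 without HFD replicate 5. With the mitochondrial share as a covariate the counts were 298 (139 higher, 159 lower) and 0. TPM values gave 64 for the diet effect, 38 higher and 26 lower, and 2471 higher and 105 lower for the UB-NP effect. The medians of all genes were then -0.151 and 0.454, against -0.082 and -0.079 with counts.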

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

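The tests of clock genes by time of day, of immune markers against other cell types, of other splits of the Uro and HFD libraries, of permuted labels for opposed and shared calls, and of permuted residuals for the interactions were chosen after the results were seen; the other tests were written down first.

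Chance sets about 1 in 20 groups apart by the measure used here, the gap of 1 library to the nearest of the others over the range of its group. Of 24 groups of library measures 3 stood apart. NC replicate 3 had 5.226% of its counts on ribosomal RNA genes, UB replicate 1 had a mitochondrial share of 51.98%, and HFD replicate 1 a total of 17.72 M (mega) counts. For named genes, 81 of 821 pairs of gene and group stood apart (9.87%), and the libraries concerned were MC replicate 5 in 11 genes, NC replicate 5 in 7, NFD replicate 5 in 6 and HFD replicates 1 and 2, NFD replicates 3 and 4, UB replicate 1 and Uro replicate 3 in 5 each. HFD replicate 5 and NC replicate 3 stood apart in 4 each, HFD replicate 3, MC replicate 3, NC replicate 1, NFD replicate 2 and UB replicate 3 in 2 each, and MC replicates 1, 2 and 4, NC replicate 2, NFD replicate 1, UB replicates 2 and 4 and Uro replicates 2 and 4 in 1 each.

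The diet effect differed between the studies in 801 genes and the UB-NP effect in 1818 (edgeR quasi-likelihood interaction, Benjamini-Hochberg). The largest differences of the diet effect, on the log2 scale, were 5.144 for Arhgap22, 5.016 for Evi2b, 4.785 for Cxcl1 and 4.661 for Cdc20, and -8.619 for Mup15, -8.24 for Mup17, -7.298 for Mup7 and -6.639 for Mup2. Leaving out 1 library ended the call of Cdc20 in 10 of 30 fits, with edgeR adjusted p of 0.051 to 0.0793, and that of Arhgap22 without NC replicate 4 (0.0591). Those of the UB-NP effect were 6.772 for Mup15, 5.52 for Ndufb4b, 5.387 for Mup17 and 5.261 for Mup7, and -10.101 for Morf4l1-ps1, -8.512 for Pgam1-ps2, -7.589 for Sardhos and -5.475 for Ulk4. Values for Morf4l1-ps1, Pgam1-ps2 and Sardhos are fitted against groups at 0 counts and depend on the prior count.

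The first pattern is the 3836 genes called between Uro and HFD, whose libraries differ in mitochondrial share without overlap. Lower depth outside mitochondrial genes in HFD is an explanation that the values argue against. Of the 3813 calls outside mitochondrial genes and copies, 83.8% were still made in their direction after every library was thinned to 3.14 M such counts. A length bias stays open, as transcript length and fold change had a Spearman correlation of -0.423 across called genes, which are not independent replicates (bootstrap -0.448 to -0.399). Median lengths were 1785.5 bases for higher and 3431 for lower genes. The correlation was 0.158 in HFD minus NFD, 0.049 in UB minus MC, -0.167 in MC minus NC, -0.15 in UB minus NC and -0.232 in Uro minus NFD. RNA composition that moves with the mitochondrial share may contribute as well, as slopes on the share within the prevention groups foresaw the changes with a correlation of 0.583 (0.282 to 0.643 with 1 library left out). This passed the bound of 0.3 written beforehand, but permuted shares gave such values too (permutation p = 0.144), so the test cannot decide whether composition contributes. Changes with the share also cannot be told apart from an effect of UB-NPs, because the share separates Uro from HFD completely. An effect of UB-NPs, which the design names, also stays open and was not tested apart from these. A technical difference of the Uro libraries, such as a batch, cannot be told apart from it, as the labels give no batch. The mitochondrial share was at most 21.6% in Uro libraries and at least 59.1% in HFD libraries.

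The second pattern is the clock genes in UB against MC. A difference in the hour of sampling is consistent with evening genes at a median of 1.465 and morning genes at -1.698, since a shift in phase moves the arms apart. The labels give no hour of sampling, and an effect of UB-NPs on the clock itself could give the same values, so it stays open and was not tested.

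The third pattern is the higher immune markers in HFD against NFD. A lower share of hepatocyte RNA would raise markers of all other cell types alike, but macrophage markers had a median 2.491 above that of sinusoidal endothelial markers and 2.464 above that of stellate markers (permutation p = 6e-05 and 0.00031 across markers, which are not independent replicates). The sinusoidal endothelial and stellate markers themselves had medians of -0.018 and 0.008, so these 2 sets did not rise. This argues against such a loss as the whole cause. A loss as part of it stays open, since 2 of 11 hepatocyte markers were lower and 0 higher, with a median of -0.377 (camera adjusted p = 0.00369, but adjusted p = 0.386 with an estimated correlation), and markers of T and NK cells, cholangiocytes, Kupffer cells and B cells had medians of 1.95, 1.397, 0.779 and 0.595. More macrophages, or macrophages in another state, may account for the rest, a hypothesis that was not tested further.

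Other splits of the libraries were drawn to ask whether chance can be excluded. For the counts of genes it can: among 80 splits, 1, the real one, reached the count in each comparison, with the real count and the highest other at 1645 and 374 for MC minus NC, 82 and 4 for UB minus MC, 1053 and 131 for UB minus NC, 1863 and 881 for HFD minus NFD, 3836 and 2 for Uro minus HFD and 4027 and 219 for Uro minus NFD. For the interactions, effects were made equal in both studies and the residuals permuted within each. Among 40 such draws, 1, the real one, reached the counts (801 and 1 for the diet, 1818 and 2 for UB-NPs), so chance can be excluded there too. A technical difference is not excluded where it concerns single groups, or where it lies between the studies and does not cancel within them. With the mitochondrial share as a covariate the counts were 298 for the diet and 0 for UB-NPs. Permuted labels mostly called 0 genes, so that 0 opposed calls, there or in simulated groups without change, say nothing about opposition. Opposed and shared calls were therefore counted among as many genes of lowest p as the real labels called. For opposed calls this test cannot decide, since the shared high-fat libraries alone give opposed genes among those of lowest p. Of 40 permutations, the real one included, 25 reached the 39 of the prevention study (highest other 67) and 30 the 648 of the treatment study (1471). With these libraries split between the comparisons, the covariance stayed under 0 in all 10 fits, at -0.154 to -0.103 in prevention and -0.157 to -0.0677 in treatment. The split fits were not compared with permuted labels, so chance is not excluded. For shared calls chance can be excluded with the diet, where 1, the real one, reached 306 (highest other 229), but not with UB-NPs, where 3 reached 30 (45). For the numbers of lists called chance cannot be excluded, as 6 of 80 splits reached the 15 lists of MC minus NC (highest other 16), 31 the 10 of UB minus MC (21), 7 the 19 of HFD minus NFD (21) and 21 the 19 of Uro minus HFD (25).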

How the results depend on the processing

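The alternatives that concern the mitochondrial share were chosen after the shares were seen, and all others before. Libraries held about 3.14 to 19.7 M (mega) counts outside mitochondrial genes. Changes of 2-fold were recovered for 31% to 43% of simulated genes within a study, in fits with 121 to 136 calls. In UB minus MC, with 82 real calls, most changes of that size in single genes may thus have been missed. The adjustment is less strict where more genes change, so these shares do not carry over to comparisons with many more calls. In MC minus NC, with 1645 calls, the median absolute log2 fold change of called genes was 0.935, which is under 2-fold. Of 63 called lists, 14 lost the call in at least 1 fit with a library left out, and of 159 calls of named genes 23 did, each naming of a gene in a comparison counted once. The size factors of DESeq2 and leaving out the mitochondrial genes and copies changed the call of 0 named genes and ended that of 0 called lists among those still tested. Other lists were gained, as HFD minus NFD had 20 lists called with the size factors instead of 19, and still 19 without the mitochondrial genes, whose own called list was then not tested. For every change below, unless the alternative's construction shows the cause, the cause was not tested.

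With a minimum absolute log2 fold change of 1, which by construction leaves fewer genes, the counts were 725 for MC minus NC, 50 for UB minus MC, 488 for UB minus NC, 1156 for HFD minus NFD (751 higher, 405 lower), 2157 for Uro minus HFD and 2451 for Uro minus NFD. Opposed calls were then 15 in prevention and 263 in treatment, shared diet calls 136 and shared UB-NP calls 15. Without the low-count filter, UB minus MC had 129 calls and the shared UB-NP calls were 48. The DESeq2 test gave 232 for UB minus MC, 92 opposed calls in prevention, 463 shared diet calls and 99 shared UB-NP calls. Voom with sample quality weights gave 1825 for UB minus NC, 1762 for the diet interaction, 2784 for the UB-NP interaction, 1148 opposed calls in treatment and 52 shared UB-NP calls.

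Limma on log2(TPM + 1), where the mitochondrial share enters every value because columns share 1 total, gave 6904 calls for UB minus NC, 575 for HFD minus NFD, 7314 for Uro minus HFD, 9140 for Uro minus NFD and 64 for the diet interaction (38 higher, 26 lower). Higher and lower calls split as 71 to 2 for UB minus MC and 2471 to 105 for the UB-NP interaction. The median log2 fold change of all genes was 0.331 in UB minus MC, -0.151 in the diet and 0.454 in the UB-NP interaction. With counts these medians were 0.003, -0.082 and -0.079. TPM values gave 6 and 68 opposed calls, 136 shared diet calls, 52 shared UB-NP calls and 10 lists for Uro minus HFD. They turned the sign of Scd1 (0.293) and Pck1 (0.418) in Uro minus HFD.

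With the mitochondrial share as a covariate, which the groups confound with the treatment, the counts were 377 for MC minus NC, 71 for UB minus NC, 2 for Uro minus HFD, 0 for Uro minus NFD, 298 for the diet and 0 for the UB-NP interaction. Opposed calls were 15 and 0, shared diet calls 153, shared UB-NP calls 0 and lists called for Uro minus HFD 3. Over the genes called without it, the median absolute log2 fold change went from 0.935 to 0.876 in MC minus NC, from 0.961 to 0.767 in UB minus NC, from 1.07 to 0.753 in Uro minus HFD, from 1.14 to 0.77 in Uro minus NFD, from 1.52 to 1.32 in the diet and from 1.36 to 0.823 in the UB-NP interaction. The median SE went from 0.234 to 0.308, 0.235 to 0.356, 0.248 to 0.612, 0.265 to 0.677, 0.391 to 0.39 and 0.331 to 0.478 in that order, and 99.9%, 99.1%, 78.9%, 78.2%, 100% and 93.9% kept their direction. Signs turned for Fam221b (-0.265), mt-Nd6 (0.006) and Cyp1a2 (-0.674) in Uro minus HFD. Signed -log10 p-values of lists turned to -0.0943 for male-biased genes in MC minus NC, and in Uro minus HFD to -0.657 for lipoprotein, -0.362 for bile acid, -0.0995 for xenobiotic, -0.00569 for unfolded protein, -0.431 for urea cycle and -0.86 for pericentral genes and 0.75 for mitochondrially encoded genes. For mt-Nd6 and the other mitochondrially encoded genes the adjustment is circular, since the share holds their own counts. Without the library of each group with the highest share, the diet interaction had 1227 calls, and shared calls were 166 with the diet and 16 with UB-NPs. With a correlation estimated for each list, 3 lists were called in MC minus NC and 0 in UB minus MC, 0 in HFD minus NFD and 0 in Uro minus HFD.

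With each library left out in turn, the counts ranged from 923 to 2315 for MC minus NC, 20 to 109 for UB minus MC, 550 to 1589 for UB minus NC, 1108 to 2341 for HFD minus NFD, 3023 to 4537 for Uro minus HFD, 3216 to 4222 for Uro minus NFD, 495 to 1383 for the diet interaction and 1404 to 2182 for the UB-NP interaction. Opposed calls ranged from 6 to 50 and from 330 to 946, shared calls from 207 to 385 with the diet and from 11 to 44 with UB-NPs. Lists called ranged from 12 to 18, 8 to 14, 19 to 21 and 17 to 20 in MC minus NC, UB minus MC, HFD minus NFD and Uro minus HFD.

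The replicate number as a block gave 1907, 96, 1246, 1411, 3366 and 3595 calls for the 6 comparisons in that order, 714 and 1725 for the interactions, 46 and 490 opposed calls, 274 and 36 shared calls and 15, 9, 20 and 19 lists. No comparison had a correlation of deviations over 0.1 in all 5 pairs of the same number, and at most 2 of 5 libraries correlated best with their own number. A pairing by number was thus not evident, but these values do not exclude one. The block moved no count by over 1.5 times and ended the calls of 6 named genes and 2 lists.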

Other observations

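The medians of clock genes by time of day were chosen after the clock genes were seen, and the tests of gene lists and of pseudogenes before. Other gene groups moved with the diet in the treatment study. Of 9 erythroid markers 6 fell in HFD against NFD and 0 rose, or 8 fell adjusted over the list alone, with a median of -2.22 (camera adjusted p = 8.18e-08, or 0.128 with an estimated correlation). The erythroid list was also called lower in UB against MC and higher in Uro against HFD (camera adjusted p = 0.0387 and 0.0295, or 0.868 and 0.605 with an estimated correlation). Leaving out 1 library ended the first of these 2 calls in 5 of 15 fits and the second in 3. Of 21 cell cycle genes 7 rose and 1 fell, or 11 and 1 adjusted over the list alone, with a median of 1.45 (camera adjusted p = 2.18e-05; adjusted p = 0.105 with an estimated correlation and 0.0596 with TPM values), and of 11 markers of T and NK cells 4 rose, or 5 adjusted over the list alone (camera adjusted p = 0.00339; adjusted p = 0.185 with an estimated correlation). In the prevention study, 5 of 14 markers of sinusoidal endothelial cells rose in MC against NC, or 8 adjusted over the list alone (camera adjusted p = 0.00393; adjusted p = 0.154 with an estimated correlation and 0.0936 with TPM values).

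Clock genes outside UB against MC had medians of 0.65 for evening and -0.924 for morning genes in HFD against NFD, 0.304 and -1.474 in Uro against HFD, and -0.263 and -0.501 in MC against NC. In Uro against HFD the morning genes Bmal1, Npas2 and Clock were called lower (edgeR adjusted p = 0.000155, 0.000489 and 0.0106). Their log2 fold changes were -2.29, -5.149 and -0.658, and Nfil3, at 0.583, was not called. In HFD against NFD, Bmal1 and Nfil3 were called lower and Dbp, Per3, Per2 and Nr1d2 higher (edgeR adjusted p of 4.48e-05 to 0.0364). The 4 morning genes were not called in UB against MC (edgeR adjusted p of 0.127 to 0.746). The authors' deposited calls also hold a comparison of HFD with MC, with 1028 genes higher and 823 lower, that was not tested here. Across called genes, which are not independent replicates, the fold change correlated with GC content at 0.397 in MC minus NC, -0.21 in UB minus MC, 0.411 in UB minus NC, 0.031 in HFD minus NFD, 0.247 in Uro minus HFD and 0.212 in Uro minus NFD.

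Pseudogenes and long non-coding genes had a median log2 fold change in Uro against HFD that differed from that of protein-coding genes by -0.4, against -0.05 in HFD minus NFD. A lower capture of pseudogene and long non-coding transcripts in the Uro libraries might give this value, but it lies between the bounds set for and against that explanation, and the groups confound capture with treatment, so they cannot be told apart.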
